A study of Rattus norvegicus with 13 samples.

How the data were processed

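Gene expression was measured on 13 two-colour Agilent arrays of 1 rat design. On every array the Cy3 channel held RNA of untreated cells, used as a common reference, and the Cy5 channel held the sample. No dye swap is labelled. The Cy5 sample was untreated RNA on 1 array, and RNA of cells given NGF, proNGF-WT or proNGF-KR for 1 h or 4 h on 2 arrays for each of the 6 treated groups. The labels describe these pairs as biological replicates. Both 4 h arrays titled with proNGF alone are described in the labels as proNGF-WT and were used as that group. Per the labels' protocols, cells were cultured for 12 h before treatment, part of the medium was replaced at treatment, RNA was taken up in Trizol and labelled by Agilent's linear amplification. The labels do not say when the untreated cells were harvested or whether their medium was changed.

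Per the file headers, the arrays were read with Agilent Feature Extraction 9.1.3.1. The deposited scanner tables give, for each of 45018 spots, the mean intensity and the median background intensity of each channel on a linear scale and not normalized. They also give a log10 ratio of Cy5 over Cy3 that, per the file headers, Feature Extraction computed after its own background subtraction and dye normalization. The authors' value table of the series holds a log2 ratio per probe and array, made by steps not given in the sources used here. Set against the scanner ratios of the same array it correlated with r between 0.894 and 0.954 over probes. Over the brighter probes its slope on Agilent's ratio in log2 units lay between 0.957 and 0.965, so the deposited values were taken as log2 ratios of Cy5 over Cy3. Its column medians lay between -0.0172 and 0.0041. Any background correction and normalization behind these log2 values, as deposited, is not described.

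From the scanner intensities, background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with statmod 1.5.0 and data.table (1.17.8). Spots carrying an outlier flag, between 14 and 62 per array, were left out. Spots of 1 probe were averaged, which gave 41012 probes. The files pair 21283 probes with a gene name. Names were updated through the RefSeq gene list of the GRCr8 assembly, used for names alone. An accession matched for 10942 probes, a current symbol for 5035, a synonym for 3355 and a gene ID inside a provisional name for 1039, and the file's name was kept for 912. The other 19729 probes stayed unnamed.

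A probe was kept when it was well above background in Cy5 on all arrays of at least 1 group, or in Cy3 on at least 7 arrays, which left 25677 probes. A named gene was represented by its probe with the highest mean log2 intensity. The 22336 features tested are 11660 named genes and the unnamed probes, and 22067 of them had values on all arrays. Where another kept probe of a named gene gave a different answer, this is said beside the gene. The share of probes well above background ranged over arrays from 55.1% to 64.8% in Cy5 and from 53.0% to 55.8% in Cy3. With 2 arrays in a treated group and 1 untreated array, the number of arrays limits the precision.

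One linear model with 1 coefficient per group was fitted to the log2 ratios of all 13 arrays with lmFit and eBayes. The residual spread came from the 6 treated groups (residual df 6, prior df 6.70), and the lone untreated sample was assumed to vary like them. The comparisons are each treated group minus untreated, each pair of treatments at the same time, 4 h minus 1 h within each treatment, and the 4 h minus 1 h change with NGF minus that with either precursor. Benjamini-Hochberg adjustment ran over features within each comparison, and calls have an adjusted p under 0.05. Dye effects shared by all arrays cancel in these differences. All p-values quoted are two-sided, and SE is the standard error of the log2 difference from the fit.

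Genes are named by a rule: with a symbol, past the threshold and with both arrays of a group on the same side, the 10 largest and 10 smallest log2 differences for each treated group minus untreated, 8 and 8 between treatments, 5 and 5 between times, and 3 and 3 for the differences between time changes. Where no gene passed, the 3 with the smallest p are given as not passing. Members of the gene lists may be named in any comparison. A gene that was well above background on no array of 1 of the groups compared has a lower bound, written as at least N-fold. It compares the bright group's mean Cy5 value with the higher of the dim probe's own Cy5 value and the lowest value among probes well above background on that array. Cy5 values for these bounds were taken after loess and Aquantile normalization, and are open to dye bias since there was no swap. They are bounds of Cy5 signal and can exceed the fold of the background-corrected log ratio, which is given beside them.

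The 19 gene lists are immediate early genes, ERK feedback regulators, the plasminogen and matrix protease system, neuronal differentiation, cholesterol and lipid synthesis, cell cycle, hypoxia and glycolysis, stress and amino acid response, apoptosis and p53 targets, heat shock, catecholamine and chromaffin genes, neurotrophins with their receptors and convertases, NF-kappaB and inflammatory genes, ribosome biogenesis, housekeeping genes, and markers of fibroblasts, glia, adrenal cortex, and endothelial and blood cells. They were tested with camera (preset correlation 0.01, adjusted over the 19 lists of a comparison), and again with camera's estimated correlation and with fry. Of 75 camera calls over the 17 comparisons, 29 also passed with an estimated correlation and 63 with fry. The design, the rule for named genes, the lists and the alternatives were fixed before the data were examined, except the list tests with slide as a block, which were not planned.

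The scripts were tested on simulated arrays in which 200 of 22067 features were changed by known folds. For NGF minus proNGF-WT at 1 h, 92% of features changed 1.5-fold and 100% of those changed 2-fold were recovered, and for NGF 1 h minus untreated 73.6% and 98.8%. Of the calls in these comparisons 5.98% and 7.57% were false. Errors were drawn independently, with the same SD on all arrays for a feature.

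The barcodes place the arrays on 4 slides. Slide 1 held the untreated array, both NGF 1 h arrays and proNGF-WT 1 h replicate 1. Slide 2 held proNGF-WT 1 h replicate 2 and both proNGF-KR 1 h arrays. Slide 3 held both NGF 4 h arrays and proNGF-WT 4 h replicate 1, and slide 4 held proNGF-WT 4 h replicate 2 and both proNGF-KR 4 h arrays. A fixed slide term (residual df 4) was fitted for comparisons that it allows to be estimated. NGF and proNGF-KR, and proNGF-KR 1 h and untreated, shared no slide, so these comparisons are joined through 1 proNGF-WT array on each slide, with a larger SE than comparisons within slides, and their loss of calls is no check within slides. Time and slide coincide, so 4 h minus 1 h and 4 h minus untreated were run with slide as a random block, whose estimated correlation was -0.104. This block removes no slide effect from these comparisons. Other alternatives were the log ratio of a treated group tested against 0, Agilent's processed ratio, no background correction, scale normalization between arrays, the authors' value table, 2 other filters on dim probes, the mean of all kept probes of a gene, a replicate block, an intensity trend with a robust prior, and leaving out each of the 12 treated arrays. The last leaves a group of 1 array, assumed to vary like the others. Comparisons with the untreated group share its 1 array. Their overlap with no effect was simulated in 50 data sets, and since 1 array cannot be split, part of any overlap may come from it.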

Results

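PC12 cells of the SB subclone, a rat adrenal pheochromocytoma line that takes on neuronal features with NGF, were given mature NGF at 10 ng/ml or its precursor proNGF at 20 ng/ml. The precursor was either the wild-type protein (proNGF-WT) or proNGF-KR, whose furin cleavage site is altered so that it resists conversion to mature NGF. RNA taken after 1 h and after 4 h was compared with RNA of untreated cells on two-colour arrays. Each of the 6 treated groups has 2 arrays and the untreated group has 1. The question named by the series is whether NGF and proNGF act on different early transcripts. Arrays of a group correlated over features with r = 0.902 for NGF 1 h, 0.893 for proNGF-WT 1 h, 0.648 for proNGF-KR 1 h, 0.887 for NGF 4 h, 0.694 for proNGF-WT 4 h and 0.774 for proNGF-KR 4 h. The SD of 1 array around its group ranged from 0.0836 to 0.151 on the log2 scale and was highest for proNGF-KR 1 h. Some arrays correlated more with another group than with their own replicate. For proNGF-KR 1 h replicate 1, r was 0.853 and 0.900 with the proNGF-WT 1 h arrays. For proNGF-WT 4 h replicates 1 and 2, r was 0.812 and 0.830 with proNGF-KR 4 h replicate 1. Features are not independent replicates.

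After 1 h of NGF, transcripts of immediate early transcription factors were far above the untreated level. Egr1, a zinc finger transcription factor, rose 231-fold (log2 difference 7.85, SE 0.30, limma adjusted p = 8.31e-09, n = 2 against 1). Egr4 rose 25.4-fold, and its relative Egr2, not well above background in untreated cells, was at least 19.7-fold higher in Cy5 signal, with a log ratio difference of 4.03 (adjusted p = 1.57e-09). The antiproliferative gene Btg2 rose 15.5-fold, Fos 13.6-fold, Ier2 10.6-fold, the nuclear receptor gene Nr4a1 9.12-fold, Jun 7.31-fold, Atf3 7.14-fold and Arc, a regulator of synaptic AMPA receptors, 6.44-fold. Of 25 measured immediate early genes, 21 rose and 1 fell, and the counts were the same when adjusted over the list alone (camera adjusted p = 2.2e-32, 0.020 with an estimated correlation, and 0.10 with slide as a block besides). Junb (2.64), Fosl1 (1.92), Klf6 (1.74) and Klf4 (1.71) were among those that rose, given as log2 differences, and Nab2, a corepressor of Egr proteins, was the 1 that fell (-0.75).

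Other groups moved less at 1 h of NGF. Of 12 regulators that feed back on ERK signalling, 5 rose and none fell, or 7 and 0 adjusted over the list alone. Examples are Errfi1 (1.51), Dusp5 (1.45), Dusp1 (1.40) and Trib1 (1.15). The list passed camera (adjusted p = 0.0016) but not with an estimated correlation (adjusted p = 0.21). Of 26 hypoxia and glycolysis genes 8 fell and 2 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.012, 0.56 with an estimated correlation, and 0.12 against 0). The glycolytic enzyme gene Eno1 changed by -0.68, and the genes that rose were Ankrd37 (1.11) and Adm (1.04). Ankrd37 was also higher in every other treated group (0.50 to 0.92), and the list also fell by camera with either precursor at 1 h. These 2 changes are therefore not particular to NGF and may come from the untreated sample. The named genes that fell changed by about 2-fold: COX1, described in the files as cytochrome c oxidase subunit 1 (-1.35), MGC105830 (-1.25), LOC499894 (-1.17), Sacm1l (-1.13), Smad7, an inhibitor of TGF-beta signalling (-1.12), Snrpn-ps4 (-1.08), the actin-severing factor gene Cfl1 (-1.08), Hnrnpa2b1 (-1.07), Eef1a2 (-1.07) and Chchd10 (-1.07). Another probe of Hnrnpa2b1 was not called, and the COX1 call ended with Agilent's processed ratio and without NGF 1 h replicate 2. MGC105830, LOC499894, Snrpn-ps4, Cfl1, Hnrnpa2b1 and Eef1a2 were lower in every treated group, so their falls are not particular to NGF and may come from the untreated sample. In total 1814 features were higher and 1481 lower, among them 564 and 1010 named genes, of which 51 and 13 differed over 2-fold. The count of 3295 fell to 1009 without NGF 1 h replicate 1 and to 1873 without replicate 2, and was 7697 when the log ratio was tested against 0, which mixes in dye effects.

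After 4 h of NGF, Egr1 was still 37.2-fold above the untreated level (5.22, SE 0.30, adjusted p = 2.16e-07, n = 2 against 1), and genes of secreted proteases were among the highest. The collagenase gene Mmp13 rose 28-fold (4.81, SE 0.16, adjusted p = 3.29e-09). The serine protease gene Prss22 was at least 37.0-fold higher in Cy5 signal, the stromelysin genes Mmp3 and Mmp10 at least 15.7-fold and at least 7.55-fold higher, all 3 not well above background in untreated cells. Their log ratios differed by 4.64, 3.56 and 2.75. Dusp6, a phosphatase of ERK, rose 10.5-fold, the natriuretic peptide gene Nppb 7.27-fold, Tm4sf1 6.09-fold, Errfi1, an inhibitor of EGF receptor signalling, 5.99-fold, and the receptor tyrosine kinase gene Ret 5.88-fold. The size for Ret depended on the probe: its log2 difference was 2.56, and other probes, also called, were at 1.43 and 0.99. Among genes that fell, Rapgef5, an exchange factor for Rap proteins, changed by -2.30 (SE 0.15, adjusted p = 4.82e-07). It was followed by Nadk2 (-1.75), Kif26b (-1.70), Il17re (-1.44), Cc2d2a (-1.41), Klhl7 (-1.38), Ldb3 (-1.37), the transcription factor gene Ascl2 (-1.32), Mcf2l (-1.30) and the checkpoint kinase gene Chek1 (-1.30).

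By list, 8 of 12 plasminogen and matrix protease genes rose at 4 h of NGF and none fell, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-08, 0.014 with an estimated correlation). Besides the metalloproteases these included Plaur, the urokinase receptor gene (2.49), and Serpine1, the gene of its inhibitor PAI-1 (1.88). Of 12 ERK feedback regulators 9 rose and none fell, also adjusted over the list alone (4.6e-06, and 0.044 with an estimated correlation), among them Trib1 (1.49) and Spred1 (0.93). Among 25 immediate early genes 19 rose and none fell, also adjusted over the list alone (7.9e-16, and 0.044 with an estimated correlation), with Fosl1 at 2.47, Arc at 2.33, Ier3 at 2.25 and Nab2 at 1.12. Of 27 neuronal differentiation genes 13 rose and 4 fell, or 14 and 5 adjusted over the list alone. Those that rose include the kinase gene Plk2 (2.36), the neurosecretory gene Vgf (1.96), Nrn1 (1.44), Dclk1 (1.32) and neurofilament Nefl (0.71), and those that fell include Nefh (-0.50). This list passed camera (adjusted p = 0.0063) but not with an estimated correlation (adjusted p = 0.051). Of 29 cholesterol and lipid synthesis genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone, with Msmo1 at 1.82, Hsd17b7 at 1.66 and Sqle at 1.44 (adjusted p = 8.5e-06, and 0.076 with an estimated correlation). Of 31 cell cycle genes 14 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0017, and 0.048 with an estimated correlation). The replication genes Cdc6 (-1.22), Mcm6 (-1.02) and Mcm2 (-0.75) fell. In total 3172 features were higher and 3382 lower than in untreated cells, among them 1558 and 2098 named genes, of which 198 and 79 differed over 2-fold. Tested against 0 the count of 6554 was 11087.

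**Figure D1:**
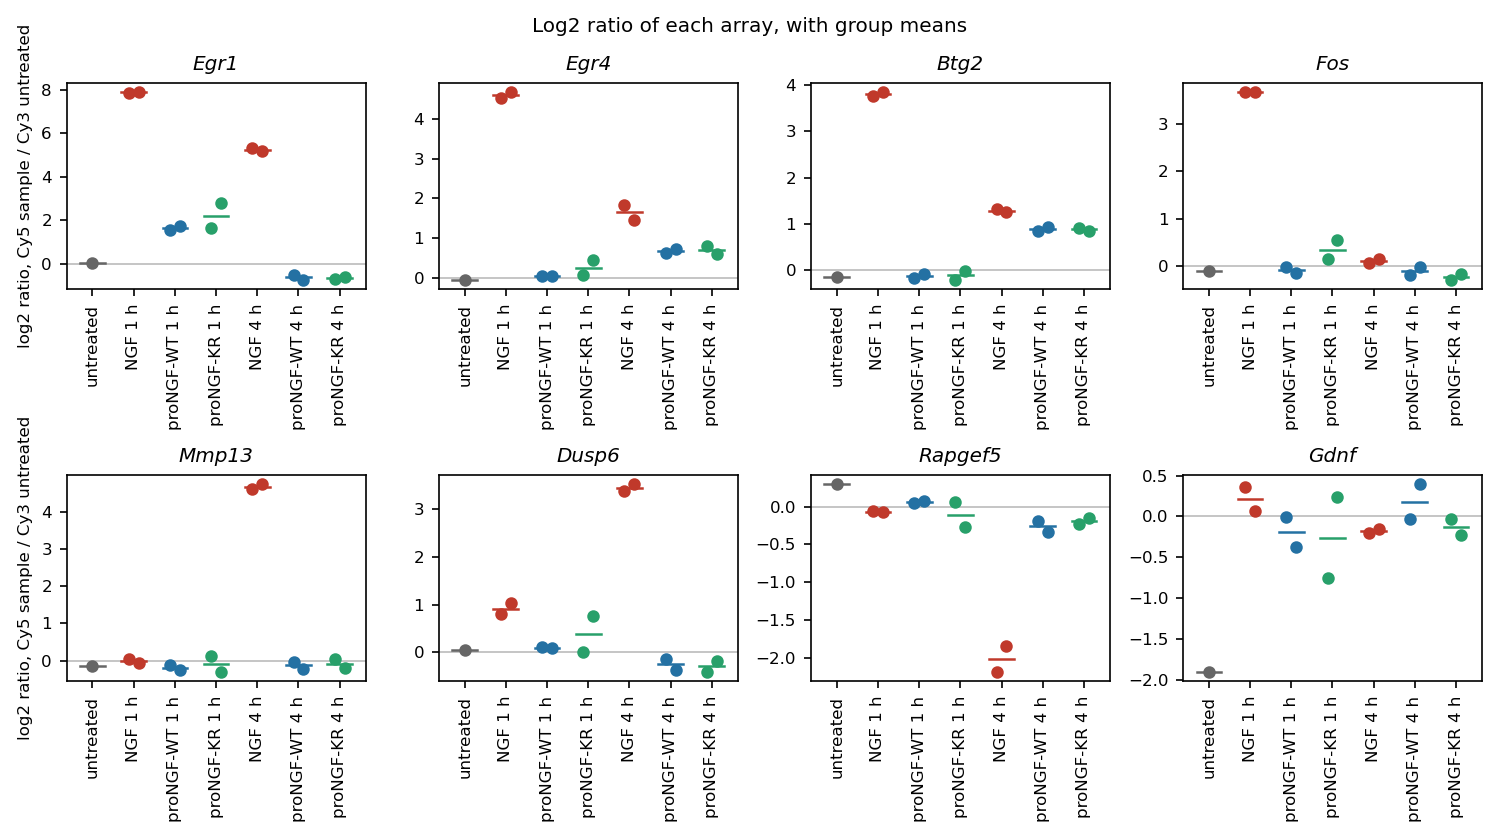
Log2 ratio of sample (Cy5) over untreated reference (Cy3) for 8 genes, as a point per array, with a line at each group's mean. Egr1, Egr4, Btg2 and Fos were highest at 1 h of NGF, while Mmp13 and Dusp6 were highest and Rapgef5 lowest at 4 h of NGF. For Gdnf the untreated array lies below all treated arrays.

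One hour of proNGF-WT raised few of the immediate early genes that NGF raised, and by less. Egr1 rose 3.07-fold (1.62, SE 0.30, adjusted p = 0.00585, n = 2 against 1), Klf6 by 0.78 and Klf4 by 0.53 on the log2 scale. These were the 3 of 25 immediate early genes that rose, and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.98). Ier2 (-0.46) and Nab2 (-0.86) fell. The largest rise was that of Gdnf, a neurotrophic factor gene (1.71). Others were Stag2 (1.44), the Rho kinase gene Rock1 (1.36), Rtn4rl2 (1.32), Nek1 (1.23), Rab15 (1.21), the hyaluronan receptor gene Hmmr (1.19), Abp10 (1.17) and the olfactory receptor gene Or10am5 (1.15). The largest falls were those of MGC105830 (-1.23), Eps8l2 (-1.13), LOC499894 (-1.11), Cfl1 (-1.10), Snrpn-ps4 (-1.08), Chchd10 (-1.07), Adrm1 (-1.03), Eef1a2 (-1.02), the cytokine gene Mif (-1.01) and Pc, pyruvate carboxylase (-0.99). Of 26 hypoxia and glycolysis genes 12 fell and 1 rose, or 15 and 1 adjusted over the list alone (adjusted p = 4.4e-05, and 0.29 with an estimated correlation), with Eno1 at -0.69 and Tpi1 at -0.62. No ERK feedback regulator of 12 passed, also adjusted over the list alone.

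The rises of Gdnf, Rtn4rl2, Or10am5 and Rab15 with proNGF-WT rest on the untreated array: against the Cy3 reference their values were -0.19, -0.17, -0.05 and 0.06. Another probe of Rab15 was called the other way, and other probes of Stag2 and Hmmr were not called. In total 1700 features were higher and 1490 lower, among them 562 and 1033 named genes, 21 and 9 of them over 2-fold. The Egr1 call ended with slide as a block (1.55, SE 0.39, adjusted p = 0.054) and with an intensity trend, the Klf4 call with an intensity trend and without proNGF-WT 1 h replicate 1, and that of Ier2 in 4 alternatives. The Rtn4rl2 and Or10am5 calls also ended without replicate 1. The count of 3190 was 915 with slide as a block, 1061 without proNGF-WT 1 h replicate 1, 1152 without replicate 2 and 8201 against 0.

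With proNGF-KR at 1 h, Egr1 rose 4.57-fold (2.19, SE 0.30, adjusted p = 0.0018, n = 2 against 1), Klf6 by 0.81 and Klf4 by 0.72. Of 25 immediate early genes 3 rose and 3 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.23). Gdnf (1.64), Hmmr (1.38), Rtn4rl2 (1.35), Rab15 (1.16), Nek1 (1.13), Stag2 (1.08), Or10am5 (1.08), LOC310926 (1.05) and Aff2 (1.05) were the other named genes that rose. MGC105830 (-1.23), Snrpn-ps4 (-1.07), Cfl1 (-1.05), Eps8l2 (-1.05), Eef1a2 (-1.0), LOC499894 (-0.99), Chchd10 (-0.99), Btbd2 (-0.95), Smad7 (-0.94) and the chromogranin gene Chga (-0.93) fell. Of 26 hypoxia and glycolysis genes 6 fell and 1 rose, or 12 and 3 adjusted over the list alone (adjusted p = 0.0089, and 0.70 with an estimated correlation). Lists of 18 catecholamine genes (0 rose and 2 fell, or 0 and 4 adjusted over the list alone), 18 neurotrophins, receptors and convertases (0 and 1, or 0 and 6) and 30 cell cycle genes (0 and 2, or 0 and 0) also passed camera downward, with adjusted p = 0.036, 0.031 and 0.031, and 0.74, 0.24 and 0.24 with an estimated correlation.

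In total 1291 features were higher and 1042 lower with proNGF-KR at 1 h, among them 403 and 731 named genes, 10 and 5 of them over 2-fold. None of these 2333 was called with slide as a block, and Egr1 was at 2.05 (SE 0.51, adjusted p = 0.17), the 4 lists at adjusted p = 0.13 to 0.14. The count was 1528 without proNGF-KR 1 h replicate 2 and 7519 against 0. Replicate 2 was the array with the higher Egr1 ratio, at 2.79 against 1.63. Against the Cy3 reference Gdnf, Rtn4rl2, Or10am5, LOC310926, Aff2 and Rab15 lay at -0.26, -0.15, -0.13, -0.25, -0.08 and 0.01, and Chga at -0.03, so these calls rest on the untreated array. Another probe of Rab15 was called the other way, and other probes of Hmmr, Stag2, Aff2 and Chga did not show these changes. With Agilent's ratio the calls of Rtn4rl2, Or10am5, Stag2 and Chga ended, as did that of the catecholamine list (camera adjusted p = 0.069). Against 0 the catecholamine, neurotrophin and hypoxia lists did not pass camera (adjusted p = 0.19, 0.13 and 0.18).

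After 4 h of proNGF-WT, Egr1 was no longer above the untreated level (-0.66, not called), while Btg2 rose 2.05-fold (1.04, SE 0.11, adjusted p = 0.00119, n = 2 against 1), Arc rose by 0.98 and Srf, the serum response factor gene, by 0.78. The other named genes that rose were Gdnf (2.09), Rtn4rl2 (1.67), the splicing-related gene Rsrp1 (1.41), Or10am5 (1.32), Rab15 (1.17), LOC310926 (1.16), Aff2 (1.10), Foxc2 (1.00) and Hspbap1 (0.99). Cfl1 (-1.16), COX1 (-1.12), Lrba (-1.03), LOC499894 (-0.97), Agap1 (-0.95), the calsyntenin gene Clstn1 (-0.93), the chaperonin gene Cct6a (-0.92), RGD1564536 (-0.92), Zer1 (-0.92) and Hnrnpa2b1 (-0.91) fell. Of 25 immediate early genes 8 rose and none fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.021, and 0.71 with an estimated correlation). Of 29 cholesterol and lipid synthesis genes 5 rose and none fell, or 7 and 2 adjusted over the list alone, with Sqle at 0.75 and Msmo1 at 0.74 (adjusted p = 0.018, and 0.53 with an estimated correlation). Of 26 hypoxia and glycolysis genes 3 fell and 1 rose, or 7 and 1 adjusted over the list alone, with Vegfa at -0.73 (adjusted p = 0.021, and 0.71 with an estimated correlation).

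In total 789 features were higher and 826 lower after 4 h of proNGF-WT, among them 298 and 565 named genes, 9 and 3 of them over 2-fold. The count of 1615 was 893 with Agilent's processed ratio, 3682 with scale normalization and 5367 against 0. It was 405 and 551 without replicate 1 or 2 of this group, 938 without either proNGF-WT 1 h array, 1017 without either NGF 1 h array and 2680 without either proNGF-KR 1 h array, since all arrays share 1 estimate of the spread. LOC310926 and Aff2 lay at -0.15 and -0.03 against the Cy3 reference, and the Gdnf, Rtn4rl2, Or10am5, Rab15, Foxc2, COX1, LOC499894 and Hnrnpa2b1 calls also ended there. The COX1 and Foxc2 calls ended in many other alternatives too, those of Or10am5, Aff2 and Hnrnpa2b1 without proNGF-WT 4 h replicate 2, and those of Aff2 and Hnrnpa2b1 with Agilent's ratio. Rab15 and Aff2 lost their calls with all probes averaged: another Rab15 probe was called the other way (-0.51), and another Aff2 probe was not called (-0.15). Other probes of Lrba and Hnrnpa2b1 changed little, and 1 of 2 other Agap1 probes was called. The immediate early, cholesterol and hypoxia list calls all ended with Agilent's ratio (adjusted p = 0.051 each), and that of the hypoxia list also against 0 (adjusted p = 0.86).

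After 4 h of proNGF-KR, Btg2 rose 2.05-fold (1.04, SE 0.11, adjusted p = 0.00286, n = 2 against 1), Arc by 0.99 and Srf by 0.85, and Egr1 was at -0.67 and not called. Gdnf (1.78), Rtn4rl2 (1.45), Rsrp1 (1.35), Or10am5 (1.06), LOC310926 (1.04), Foxc2 (0.96), Hspbap1 (0.95) and Nek1 (0.94) were the other named genes that rose. Cfl1 (-1.04), Lrba (-0.99), Agap1 (-0.99), Bbx (-0.98), Hnrnpul2 (-0.91), LOC499894 (-0.89), Chga (-0.89), Cct6a (-0.89), the nuclear import gene Tnpo1 (-0.87) and Zer1 (-0.87) fell. Of 25 immediate early genes 8 rose and none fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.012, and 0.58 with an estimated correlation). Of 29 cholesterol and lipid synthesis genes 4 rose, or 7 and 2 falling adjusted over the list alone (adjusted p = 0.035, and 0.58 with an estimated correlation). Of 26 hypoxia and glycolysis genes 2 fell and 1 rose, or 5 and 2 adjusted over the list alone, with Vegfa at -0.77 (adjusted p = 0.012, and 0.58 with an estimated correlation). Of 27 neuronal differentiation genes 2 fell and none rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.031, and 0.37 with an estimated correlation). With Agilent's ratio the immediate early, cholesterol and neuronal list calls ended (adjusted p = 0.063, 0.10 and 0.063), and against 0 those of the hypoxia and neuronal lists (0.59 and 0.63).

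In total 704 features were higher and 688 lower after 4 h of proNGF-KR, among them 244 and 471 named genes, 6 and 1 of them over 2-fold. The count of 1392 was 754 with Agilent's processed ratio, with 61.1% of calls higher against 50.6%, 3329 with scale normalization and 5736 against 0. It was 78 without replicate 1 of this group and 813 without replicate 2, 906 without either NGF 1 h array, 870 without either proNGF-WT 1 h array and 2468 without either proNGF-KR 1 h array. Against the Cy3 reference Gdnf, Rtn4rl2, Or10am5, LOC310926 and Chga lay at -0.13, -0.05, -0.14, -0.26 and 0.01, and the calls of Foxc2 and LOC499894 ended. Without replicate 1 the calls of Gdnf, Rtn4rl2, Or10am5, Foxc2, Nek1, Lrba, Bbx, Hnrnpul2, LOC499894, Chga and Tnpo1 ended, those of Foxc2, Chga and Or10am5 also ended in many other alternatives, and that of Rtn4rl2 with Agilent's ratio. Other probes of Chga, Lrba and Tnpo1 changed little, another Bbx probe was not called, and 1 of 2 other Agap1 probes was called.

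**Figure D2:**
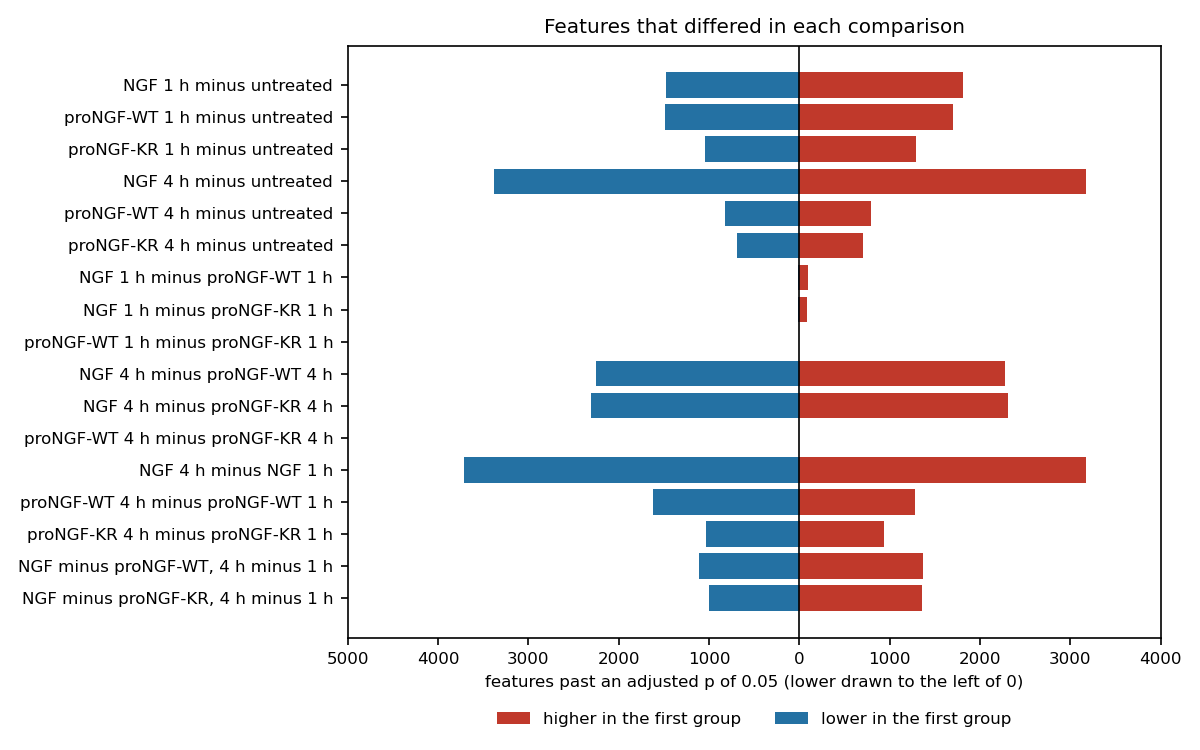
Number of features higher (red, right) and lower (blue, left) in the first-named group at an adjusted p under 0.05 in each of the 17 comparisons. NGF at 4 h against untreated gave 3172 and 3382, and proNGF-WT against proNGF-KR gave 0 at both times.

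The 6 treated groups shared many calls against the untreated array. Of 22067 features with values on all arrays, 531 were called the same way in all 6 groups, 281 higher and 250 lower, against a mean of 0.02 in simulated data without effects. Named genes made up 18.9% of the former and 67.6% of the latter, beside 52.0% of all features. Of the falls named above, those of Cfl1, LOC499894, MGC105830, Snrpn-ps4, Hnrnpa2b1, Eef1a2, Eps8l2, Mif and Btbd2 were among the 250. So were those of Lrba, Agap1, Clstn1, Cct6a, RGD1564536, Zer1, Hnrnpul2 and Mcf2l. These falls cannot be told apart from a difference of the untreated sample. NGF and proNGF-WT at 1 h shared 2184 calls in the same direction, where independent lists would share 136.3 higher and 98.3 lower, and simulated groups without effects shared 0.04. Their log2 differences had a covariance of 0.0729 against 0.0107 simulated (r = 0.832 against 0.667, across features). For NGF with proNGF-WT and with proNGF-KR at 4 h, r was 0.624 and 0.612, below the 0.667 of simulated data. That simulated value is set by the shared untreated array, and differences particular to NGF lower r. A lower r therefore does not mean less sharing, and the covariances at 4 h were above the 0.0107 simulated. For NGF with proNGF-KR at 1 h r was 0.867, and between the precursors it was 0.944 at 1 h and 0.948 at 4 h. Sharing was 1875 for NGF and proNGF-KR at 1 h (covariance 0.0706), 2032 for both precursors at 1 h (0.0716), 1288 for NGF and proNGF-WT at 4 h (0.062), 1112 for NGF and proNGF-KR at 4 h (0.0594) and 1118 for both precursors at 4 h (0.0579). Since all these comparisons use the 1 untreated array, part of the excess may come from it. Simulated data without effects hold few calls in any comparison, so their shared counts are near 0 in advance. Those counts do not give the overlap to expect of groups with many calls that share 1 untreated array. Against 0 the number of shared genes between comparisons in all 6 groups was 1481, and with Agilent's processed ratio 326.

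Treatments at the same time can be compared without the untreated array. At 1 h, NGF-treated cells had 75.2 times the Egr1 transcript of proNGF-WT-treated cells (6.23, SE 0.25, adjusted p = 8.85e-09, n = 2 against 2). Egr4 was 23.9-fold, Btg2 15.2-fold, Ier2 14.6-fold, Fos 13.4-fold, Nr4a1 9.92-fold and Arc 8.49-fold higher, and Egr2 at least 20.7-fold higher in Cy5 signal (log ratio difference 3.89), not being well above background with proNGF-WT. Of 25 immediate early genes 21 were higher with NGF and none lower, or 22 and 0 adjusted over the list alone (camera adjusted p = 1.4e-99, 8.7e-04 with an estimated correlation), with a median log2 difference of 1.87 and of 1.84 within slides. Klf4 (1.18) and Klf6 (0.97), which also rose with proNGF-WT, were among the 21. Of 12 ERK feedback regulators 4 were higher, or 7 adjusted over the list alone (4.3e-10, and 0.017 with an estimated correlation), with Errfi1 at 1.65, Dusp1 at 1.19 and Dusp5 at 1.16, while Dusp6 was at 0.81 and did not pass. Of 23 stress and amino acid response genes 5 were higher, or 9 adjusted over the list alone (4.4e-11, and 0.041 with an estimated correlation). These last 2 lists had adjusted p = 0.066 and 0.063 when slide was also a block.

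Lists of cholesterol synthesis (3 of 30 higher, or 4 adjusted over the list alone; adjusted p = 1.4e-04), hypoxia and glycolysis (2 of 26, or 3; 2.4e-04), apoptosis (2 of 29 higher, or 5 and 1 lower; 0.0059) and matrix proteases (1 of 12, or 2; 0.018) passed camera at 1 h of NGF over proNGF-WT, but had adjusted p = 0.125, 0.21, 0.12 and 0.12 with an estimated correlation, and the protease call also ended with Agilent's ratio (0.052). Few features were lower with NGF. The named ones were COX1 (-2.15), the olfactory receptor gene Or5b123b (-1.25), Lrrcc1 (-0.77), Lrr1 (-0.49) and Zfp12 (-0.38), of which the last 3 lost their calls with slide as a block and in other alternatives. Or5b123b lost its call without NGF 1 h replicate 2 or proNGF-WT 1 h replicate 1. In total 100 features were higher with NGF and 15 lower, among them 76 and 5 named genes. The count of 115 was 57 with slide as a block, 60 without NGF 1 h replicate 2 and 64 without either proNGF-WT 1 h array. Within slides Egr1 was at 6.30, Fos at 3.68 and COX1 at -2.07.

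Against proNGF-KR at 1 h, the same kind of gene led. Egr1 was 50.5-fold higher with NGF (5.66, SE 0.25, adjusted p = 2.62e-08, n = 2 against 2), Egr4 20.5-fold, Btg2 15.1-fold, Ier2 13.7-fold, Fos 9.96-fold, Arc 9.33-fold and Junb 6.35-fold, with Egr2 at least 19.3-fold higher in Cy5 signal (log ratio difference 3.76). All in all 21 of 25 immediate early genes were higher and none lower, also adjusted over the list alone (camera adjusted p = 4.3e-114, 5.9e-04 with an estimated correlation, median 1.74, and 1.75 with slide as a block). Of 12 ERK feedback regulators 4 were higher, or 7 adjusted over the list alone (5.4e-09, 0.023 with an estimated correlation and 0.12 with slide as a block besides), and of 23 stress and amino acid response genes 4, or 8 adjusted over the list alone (1.6e-10, 0.047, and 0.083 with the block besides). Cholesterol synthesis (3 of 29, or 5 and 1 lower adjusted over the list alone) and apoptosis genes (0 of 29, or 3) had adjusted p = 6.4e-04 and 0.030, and 0.21 each with an estimated correlation. They did not pass with slide as a block (0.33 and 0.12). COX1 (-2.21), Or5b123b (-1.27), Rbak (-0.56) and Zfp12 (-0.40) were lower with NGF, and with slide as a block COX1 (-2.04, adjusted p = 0.24), Rbak and Zfp12 were not called. The Or5b123b call ended with Agilent's ratio and without NGF 1 h replicate 2. In total 86 features were higher and 11 lower, with 67 and 4 named genes. The count of 97 was 21 with slide as a block, 58 without NGF 1 h replicate 1 and 44 without replicate 2.

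At 4 h the difference between NGF and proNGF-WT covered far more features than at 1 h. Egr1 was 58.6-fold higher with NGF (5.87, SE 0.25, adjusted p = 7.88e-09, n = 2 against 2), Mmp13 27.7-fold (4.79, SE 0.13, adjusted p = 2.23e-10), Dusp6 12.9-fold, Plk2 5.89-fold and Tm4sf1 5.82-fold. Prss22, Mmp3 and Mmp10, not well above background with proNGF-WT, were at least 35.7-fold, 15.2-fold and 7.56-fold higher in Cy5 signal, with log ratio differences of 4.55, 3.50 and 2.82. Lower with NGF were Rapgef5 (-1.75), Ascl2 (-1.47), Il17re (-1.37), Nadk2 (-1.30), C2h5orf34 (-1.24), Cc2d2a (-1.20), Kif26b (-1.17) and Cdc6 (-1.15). Of 12 matrix protease genes 9 were higher and none lower, or 10 and 0 adjusted over the list alone, including Plaur (2.39) and Serpine1 (2.24), with camera adjusted p = 4.0e-12 and 0.0050 with an estimated correlation. Of 27 neuronal differentiation genes 12 were higher and 1 lower, or 13 and 1 adjusted over the list alone (3.7e-07, 0.0087 with an estimated correlation), with Vgf at 2.34, Nrn1 at 1.58 and Dclk1 at 1.53. Of 31 cell cycle genes 12 were lower and none higher, or 15 and 0 adjusted over the list alone (3.7e-07, 0.0087 with an estimated correlation), including Mcm2 (-0.71) and E2f1 (-0.51).

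Immediate early genes (19 of 25 higher, none lower, also adjusted over the list alone; camera adjusted p = 3.5e-17, 0.020 with an estimated correlation) and ERK feedback regulators (9 of 12 higher and 1 lower, also adjusted over the list alone; 1.3e-07, 0.018) were likewise higher at 4 h of NGF than of proNGF-WT, with Fosl1 at 2.21, Errfi1 at 1.94, Trib1 at 1.54 and Arc at 1.35. Fos (0.21) and Atf3 (-0.04), prominent at 1 h, did not pass at 4 h. Cholesterol synthesis genes (13 of 30 higher and 1 lower, or 15 and 4 adjusted over the list alone; 5.7e-05) included Hsd17b7 (1.19), Ldlr (1.10) and Msmo1 (1.08), but did not pass with an estimated correlation (adjusted p = 0.11). Stress response genes (5 of 23 higher, or 5 and 1 lower; 0.0016) did not either (adjusted p = 0.24). In total 2279 features were higher and 2246 lower, among them 1429 and 1327 named genes, of which 153 and 20 differed over 2-fold. With slide as a block the count of 4525 was 2496, Mmp13 was at 4.70 and Rapgef5 at -1.82 within slides, the list medians were 0.75 for proteases, 0.22 for neuronal genes and -0.21 for the cell cycle, and the immediate early and ERK lists had adjusted p = 0.054 each with an estimated correlation.

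The comparison of NGF with proNGF-KR at 4 h gave 2310 higher and 2311 lower features, with 1463 and 1334 named genes, of which 156 and 21 differed over 2-fold. Egr1 was 59.1-fold higher with NGF (5.89, SE 0.25, adjusted p = 7.58e-09, n = 2 against 2), Mmp13 26.8-fold, Dusp6 13.3-fold, Cited2 6.19-fold and Plk2 6.04-fold. Prss22 and Mmp3 were at least 36.1-fold and 15.3-fold higher in Cy5 signal (log ratio differences 4.44 and 3.47), and Mmp10, well above background on 1 of 2 proNGF-KR arrays, was at 2.90. Lower with NGF were Rapgef5 (-1.82), Ascl2 (-1.49), Nadk2 (-1.44), Il17re (-1.28), C2h5orf34 (-1.24), Kif26b (-1.21), Coq8a (-1.16) and Cc2d2a (-1.16). Matrix proteases (9 of 12 higher, or 10 adjusted over the list alone; camera adjusted p = 1.7e-12, 0.0046 with an estimated correlation), neuronal differentiation genes (13 of 27 higher, or 15 and 1 lower; 1.7e-07, 0.0066), cell cycle genes (13 of 31 lower, or 15; 1.2e-07, 0.0066), immediate early genes (18 of 25 higher, or 20; 8.5e-17, 0.021) and ERK feedback regulators (9 of 12 higher, also adjusted over the list alone; 1.7e-07, 0.020) differed in the same direction as from proNGF-WT, the last 2 with adjusted p = 0.058 each when slide was a block besides an estimated correlation. Cholesterol synthesis (13 of 29, or 14 and 1 lower; 7.4e-06), stress response (6 of 23, or 7; 3.3e-04) and heat shock genes (6 of 14 and 1 lower, in both adjustments; 0.049) had adjusted p = 0.080, 0.17 and 0.43 with an estimated correlation. With slide as a block 875 features were called where the main fit called 4621, 65.5% of them higher in place of 50%. Mmp13 was then at 4.56, Rapgef5 at -1.96, the protease list at a median of 0.88 and the heat shock list did not pass (adjusted p = 0.13). Without proNGF-KR 4 h replicate 2 the count was 2885.

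**Figure D3:**
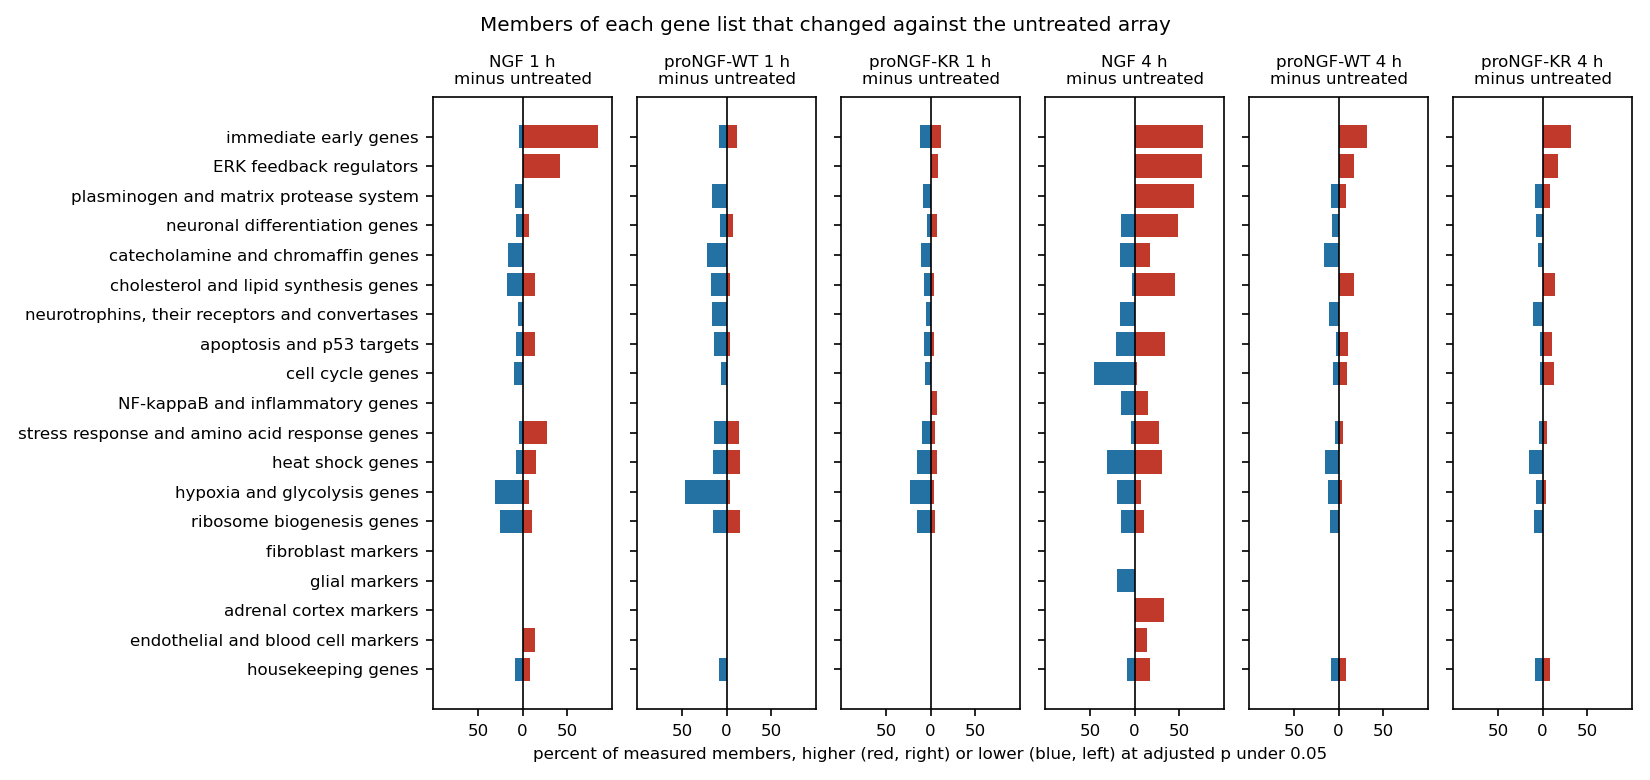
Percent of the measured members of each gene list that were higher or lower than in untreated cells at an adjusted p under 0.05, for the 6 treated groups. Of the immediate early genes 21 of 25 were higher at 1 h of NGF, against 3 of 25 with either precursor.

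Between proNGF-WT and proNGF-KR, which differ in the furin site, no feature passed at 1 h or at 4 h by limma. At an unadjusted p under 0.05 there were 478 features at 1 h and 311 at 4 h, where chance would give 1116 and 1117. Counts so far below chance are no added evidence that the precursors act alike. The p-values use a spread pooled over all treated groups, which may be too wide for this comparison. Some precursor arrays correlated more with arrays of the other precursor than with their own replicate. The smallest p values at 1 h belonged to Nr4a1 (-0.69, SE 0.16), the prolyl hydroxylase gene Egln3 (-0.36) and Vegfa (-0.40), and at 4 h to B3gnt7 (0.35), Fgf22 (0.28) and Hsp90ab1-ps5 (0.29), none passing. Egr1 at 1 h was 0.50 lower within slides with proNGF-WT, which did not pass. The 95% interval reached 0.203 to either side on the log2 scale in the median, at both times, and intervals within 2-fold in either direction covered 99.96% of features at 1 h and 99.99% at 4 h. These intervals rest on the same pooled spread, so their stated coverage may not hold here. In simulated data 93.6% of features changed 1.5-fold were recovered in this comparison at 1 h and 90.8% at 4 h. Of the simulated calls 7.46% and 7.58% were false. The simulation gave all arrays the same SD for a feature, whereas the SD of 1 array was 0.151 for proNGF-KR 1 h and 0.0844 for proNGF-WT 1 h. The simulated recovery may therefore not hold for this comparison. The count at 1 h became 3 without proNGF-KR 1 h replicate 1 and 1 without proNGF-WT 1 h replicate 2, and was 0 in all alternatives at 4 h. By camera, immediate early genes (0 of 25 passing, or 3 lower adjusted over the list alone; median -0.11) and hypoxia genes (0 of 26, or 2 lower; -0.07) were lower with proNGF-WT at 1 h (adjusted p = 1.5e-05 and 3.0e-05), but not with an estimated correlation (adjusted p = 0.34 each).

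Between 1 h and 4 h of NGF, the leading genes changed over. Mmp13 rose 25.5-fold (4.67, SE 0.13, adjusted p = 2.76e-10, n = 2 against 2), Sh2b3 5.89-fold, and Prss22, Mmp3 and Mmp10 at least 38.3-fold, 16.1-fold and 8.04-fold in Cy5 signal (log ratio differences 4.49, 3.39 and 2.85). Fos changed by -3.55 (SE 0.12, adjusted p = 1.03e-09), Egr4 by -2.97, Egr2 by -2.88, Egr1 by -2.63 and Atf3 by -2.55. Among 25 immediate early genes 16 fell and 6 rose, or 17 and 6 adjusted over the list alone (camera adjusted p = 8.9e-07, and 0.15 with an estimated correlation), and among those that rose Nab2 was at 1.87. Matrix proteases (9 of 12 rose, also adjusted over the list alone; 3.0e-09, 0.0098 with an estimated correlation) and neuronal differentiation genes (14 of 27 rose and 3 fell, or 15 and 4; 2.8e-04, 0.039) included Plaur (2.42), Vgf (2.03) and Nrn1 (1.26). Cholesterol synthesis (17 of 30 rose and 1 fell, or 18 and 1; 2.0e-07), ERK feedback (7 of 12 and 1, or 7 and 2; 0.0081) and the cell cycle list (11 of 31 fell and 1 rose, in both adjustments; 0.042) had adjusted p = 0.079, 0.15 and 0.15 with an estimated correlation, and the cell cycle call also ended with Agilent's ratio (0.081). In total 3176 features rose and 3713 fell, with 2017 and 2022 named genes. Time coincides with slide here, and time in culture is part of the comparison, as no untreated samples per time are labelled. Without NGF 1 h replicate 1 the count of 6889 was 4399, and without replicate 2 it was 4472.

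From 1 h to 4 h of proNGF-WT, Arc rose 2.61-fold (1.38, SE 0.11, adjusted p = 8.86e-05, n = 2 against 2), Rsrp1 2.54-fold, Hspbap1 2.02-fold, Btg2 2.01-fold and Srf 1.98-fold. Egr1 changed by -2.27 (SE 0.25, adjusted p = 5.15e-04), COX1 by -1.92, Fem1c by -1.42, Or5b123b by -1.19 and the splicing factor gene Srsf5 by -1.17, and for Fem1c and Srsf5 1 of 2 other probes was called. Cholesterol synthesis genes (14 of 30 rose and 1 fell, or 19 and 2 adjusted over the list alone; camera adjusted p = 7.4e-08), immediate early genes (10 of 25 and 2, or 10 and 3; 0.0090), cell cycle genes (7 of 31 and 1, in both adjustments; 0.0090), hypoxia genes (7 of 26 and 1, or 8 and 1; 0.011) and apoptosis genes (8 of 29 and 3, or 9 and 4; 0.049) rose by camera, with adjusted p = 0.15, 0.47, 0.15, 0.47 and 0.38 with an estimated correlation, and the apoptosis call also ended with Agilent's ratio (0.097). In total 1281 features rose and 1619 fell, with 854 and 788 named genes. The count of 2900 was 1313 with Agilent's ratio, of which 56.2% rose in place of 44.2%, 400 without proNGF-WT 1 h replicate 1, 210 without replicate 2 and 216 without proNGF-WT 4 h replicate 2.

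With proNGF-KR, Arc rose 2.88-fold from 1 h to 4 h (1.52, SE 0.11, adjusted p = 5.26e-05, n = 2 against 2), Rsrp1 2.56-fold, Srf 2.14-fold, Hspbap1 2.10-fold and Btg2 1.99-fold. Egr1 changed by -2.86, Fem1c by -1.37, COX1 by -1.21, Rbbp6 by -1.19 and Klf6 by -1.16, and 1 of 2 other probes each of Srf and Fem1c was called. Cholesterol synthesis genes (9 of 29 rose and 1 fell, or 12 and 1 adjusted over the list alone; camera adjusted p = 2.8e-06) and cell cycle genes (4 of 30 and 1, or 10 and 1; 1.9e-04) rose, and neuronal differentiation genes fell (5 of 27 and 1 rose, or 8 and 2; 0.047), with adjusted p = 0.15, 0.079 and 0.15 with an estimated correlation, and the neuronal call also ended with Agilent's ratio (0.13). In total 931 features rose and 1035 fell, with 602 and 586 named genes. Slide as a random block removes no slide effect from this comparison, since time and slide coincide. The count of 1966 was 1113 with Agilent's ratio, 3300 with slide as a random block, 960 without proNGF-KR 1 h replicate 1, and 471 and 430 without proNGF-KR 4 h replicate 1 or 2. COX1 lost its call without these 3 arrays and with Agilent's ratio.

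The change from 1 h to 4 h differed between NGF and proNGF-WT for 1373 features in the positive and 1114 in the negative direction, with 866 and 692 named genes. Mmp13 (4.61, SE 0.19, adjusted p = 1.98e-08), Prss22 (4.45) and Mmp3 (3.29) lead the former, and Egr4 (-3.61), Fos (-3.53) and Btg2 (-3.53) the latter. Prss22 and Mmp3 were well above background at 4 h of NGF alone, so their values are no folds. Against proNGF-KR the counts were 1360 and 998, with 869 and 582 named genes, and the values 4.67 for Mmp13, 4.44 for Prss22, 3.46 for Mmp3, -3.51 for Btg2, -3.42 for Egr4 and -2.98 for Fos. Arc, which fell from 1 h to 4 h of NGF and rose with either precursor, differed by -1.74 and -1.88. Against proNGF-WT and proNGF-KR, matrix proteases (9 of 12 positive both times, also adjusted over the list alone; camera adjusted p = 0.0052 and 0.0041 with an estimated correlation), neuronal differentiation genes (10 and 11 of 27, or 13 and 14; 0.0080 and 0.0048) and cell cycle genes (9 of 31 and 9 of 30 negative, or 14 and 13; 0.0093 and 0.0048) differed, and immediate early genes (3 positive and 15 negative of 25, or 4 and 17; 4 and 15, or 4 and 15) had 0.056 and 0.089 with an estimated correlation. ERK feedback regulators (6 of 12 positive and 1 negative both times, in both adjustments) had 0.19 and 0.11, and cholesterol genes against proNGF-KR (9 of 29 and 1, in both adjustments) 0.30. With slide as a block 749 and 134 features were called, where the main fit called 2487 and 2358. Without 1 array the first count was 1364 (NGF 1 h replicate 1), 1441 (NGF 1 h replicate 2), 1556 (proNGF-WT 1 h replicate 1), 1309 (proNGF-WT 1 h replicate 2) and 1480 (proNGF-WT 4 h replicate 2), and the second 1321 and 1422 (NGF 1 h replicates 1 and 2) and 1495 (proNGF-KR 4 h replicate 2).

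Lists that passed camera in no comparison with untreated cells include the markers of other cell types. None of 3 fibroblast markers passed in any treated group, 1 of 5 glial markers fell at 4 h of NGF (Mbp), 1 of 3 adrenal cortex markers rose there (Scarb1), and 1 of 7 endothelial and blood cell markers, Cd68, rose at 1 h and 4 h of NGF, at 1 h not with Agilent's ratio or without either NGF 1 h array. Of 12 housekeeping genes 2 rose and 1 fell at 4 h of NGF, and at most 1 in either direction in each other group. Of 13 NF-kappaB and inflammatory genes 2 rose and 2 fell at 4 h of NGF, 1 rose with proNGF-KR at 1 h, and none passed in the other 4 groups. Of 20 ribosome biogenesis genes 2 rose and 5 fell at 1 h of NGF and 2 rose and 3 fell at 4 h, and of 13 heat shock genes 4 rose and 4 fell at 4 h of NGF.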

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

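Differences between treatments in their change from 1 h to 4 h were tested as planned, while 7 of the 8 tests of explanations below were chosen after the results were seen, and the test of a partial NGF response was written before. The change over time with NGF differed from that with proNGF-WT for 2487 features. Mmp13 (4.61), Prss22 (4.45) and Mmp3 (3.29) gained more with NGF, and Egr4 (-3.61), Fos (-3.53) and Btg2 (-3.53) differed in the negative direction. Against proNGF-KR, 2358 features differed, with Mmp13 at 4.67, Prss22 at 4.44, Mmp3 at 3.46, Btg2 at -3.51, Egr4 at -3.42 and Fos at -2.98. Fos and Egr4 were high at 1 h of NGF and had fallen by 4 h, when the proteases had risen, while either precursor moved these genes little at 1 h.

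All 6 treated groups differed from the untreated array in a common set of features. Group medians were at least 0.5752 in the common direction, a size partly set by choosing features called against that array. An error of the untreated array as the whole cause is argued against by the treated arrays. Over features chosen in the other 5 groups, the ratios of each to the Cy3 reference had medians of at least 0.2031 in that direction. The untreated array's own median over the common set was -0.2681, but choosing features by calls against that array favours such a value. Over 1977 features called the same way against Cy3 in all precursor groups, without that array, its median was 0.0418. The NGF arrays, whose calls were not used there, had medians of 0.3589 to 0.4054. Slide is argued against by the treated arrays on the untreated array's slide, over features chosen in groups with no array on it. They were shifted from the untreated array by at least 0.6225, part of which the choice sets, since it used that array. Their ratios to the Cy3 reference, which the choice did not use, had medians of 0.3225 to 0.4048 in the common direction. The untreated array on the same slide lay at -0.2639, a value that the choice favours, since it used that array. A property of the single untreated RNA sample, its handling, or a dye effect that its array missed, cannot be told apart from a response common to all treatments. Genes lower in all 6 groups, such as Cfl1 (-0.98 to -1.16), belong to this common set too. Genes whose rise appears against that array alone, such as Gdnf and Rtn4rl2, are best left aside until further untreated samples are measured.

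Egr1, Klf4 and Klf6 were higher after 1 h of either precursor, though with slide as a block the Egr1 call ended for both and the Klf4 and Klf6 calls for proNGF-KR. Cleavage of proNGF-WT by furin is argued against, since the mean of the 3 genes was no higher with proNGF-WT than with the cleavage-resistant form: the upper 95% limit of the difference was 0.0794. A small amount of mature NGF in both preparations cannot be told apart from an effect of the precursor, since the dose response of each gene is unknown: over 25 immediate early genes the NGF response had a rank correlation of 0.3285 (p = 0.109) with the proNGF-WT ratios to Cy3 and of 0.4785 (p = 0.0156) with those of proNGF-KR, with no array on both sides. The medium change given with every treatment cannot be told apart either, because 0 arrays are labelled as untreated with fresh medium.

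The proNGF-KR 1 h replicates lay further apart than those of other groups (r = 0.648). Replicate 1 correlated more with the proNGF-WT 1 h arrays (0.853 and 0.900) than with replicate 2. Replicate 2 correlated most with NGF 1 h replicate 1 (0.806), and at 0.779 and 0.736 with the proNGF-WT 1 h arrays. A swap with an NGF 1 h array is argued against: the higher of the proNGF-KR medians of immediate early genes was 7.35% of the lower NGF median. A partial NGF response on 1 array is argued against as the source of the spread, because the SD of 1 array stayed at 0.1345 over 9525 features with p above 0.5 between NGF and proNGF-WT at 1 h, above the 0.0806 to 0.1127 of other groups. Some technical difference between these arrays is left as a candidate that was not tested.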

How the results depend on the processing

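The alternatives were chosen before the results were seen, except the gene list tests with slide as a block, which were not planned. The cause of the shifts the alternatives made was not tested. Testing the log ratio against 0, which leaves dye effects in, raised the counts against untreated from 3295 to 7697 (NGF 1 h), 3190 to 8201 (proNGF-WT 1 h), 2333 to 7519 (proNGF-KR 1 h), 6554 to 11087 (NGF 4 h), 1615 to 5367 (proNGF-WT 4 h) and 1392 to 5736 (proNGF-KR 4 h). Of 120 pairs of a named gene and a comparison, 92 kept their call, 13 lost it and 15 changed sign, from 6 genes: Gdnf (-0.1906, -0.2613 and -0.1276 with proNGF-WT 1 h, proNGF-KR 1 h and proNGF-KR 4 h), Rtn4rl2 (-0.1745, -0.1491, -0.0465), Or10am5 (-0.0481, -0.1256, -0.1408), LOC310926 (-0.252, -0.1466 and -0.2639 with proNGF-KR 1 h, proNGF-WT 4 h and proNGF-KR 4 h), Aff2 (-0.0845 and -0.0343 with proNGF-KR 1 h and proNGF-WT 4 h) and Chga (0.0073 with proNGF-KR 4 h).

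With a fixed slide term the counts were 915 for proNGF-WT 1 h and 0 for proNGF-KR 1 h against untreated, 57 for NGF minus proNGF-WT and 21 for NGF minus proNGF-KR at 1 h, 2496 and 875 for these at 4 h, and 749 and 134 for the differences in change over time. Of the calls, 65.5% were higher for NGF minus proNGF-KR at 4 h in place of 50%, and 82.8% in place of 57.7% for its difference over time. With slide as a random block, whose estimated correlation was -0.104, proNGF-KR 4 h minus 1 h gave 3300. This block removes no slide effect there, since time and slide coincide, so the higher count is no check on slide. Agilent's processed ratio gave 893 and 754 for proNGF-WT and proNGF-KR 4 h against untreated (61.1% higher for the latter in place of 50.6%), and 1313 (56.2% higher in place of 44.2%) and 1113 for 4 h minus 1 h of the precursors. Scale normalization gave 3682 and 3329, and the replicate block 1003 and 920, for the precursors at 4 h against untreated. Differences between replicates correlated across groups with a median r of 0.017, from -0.571 to 0.437 over 15 pairs, 5 of them above 0.1. Replicate numbers thus did not pair samples in a common way. Some groups still shared differences between their arrays, in either direction, and the source of these was not tested.

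Leaving out 1 array at a time gave 1009 to 4205 features for NGF 1 h, 1061 to 4063 for proNGF-WT 1 h, 1528 to 3359 for proNGF-KR 1 h, 5067 to 7438 for NGF 4 h, 405 to 2680 for proNGF-WT 4 h and 78 to 2468 for proNGF-KR 4 h, each against untreated. For NGF minus proNGF-WT it gave 60 to 165 at 1 h and 3033 to 5141 at 4 h, for NGF minus proNGF-KR 44 to 144 and 2885 to 5290, and for proNGF-WT minus proNGF-KR 0 to 3 and 0 to 0. The 4 h minus 1 h counts were 4399 to 7738 for NGF, 210 to 3965 for proNGF-WT and 430 to 2800 for proNGF-KR, and the differences in change over time 1309 to 3103 and 1321 to 2871. The share higher went to 75.2% from 87.0% for NGF minus proNGF-WT at 1 h without either proNGF-KR 1 h array, to 69.4% from 88.7% for NGF minus proNGF-KR at 1 h without proNGF-KR 1 h replicate 2, and to 59.2% for proNGF-WT 4 h minus 1 h without proNGF-WT 1 h replicate 1. Of 219 pairs of a named gene and a comparison, 201 to 218 kept their call.

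Of 75 gene list calls, 29 passed with an estimated correlation. The number of shared genes between comparisons, 531 in all 6 groups, was 1481 against 0 and 326 with Agilent's ratio. Against 0, pairs shared 5421 (NGF and proNGF-WT 1 h), 5370 (NGF and proNGF-KR 1 h), 6098 (precursors 1 h), 3771 (NGF and proNGF-WT 4 h), 3894 (NGF and proNGF-KR 4 h) and 4077 (precursors 4 h), and with Agilent's ratio the 4 h pairs shared 761, 637 and 590.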

Other observations

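The gene lists and comparisons in this part were fixed beforehand, and the test behind the group medians of all treated samples was chosen after the result was seen. At 4 h of NGF genes of cell survival and death moved in both directions. Mcl1, an antiapoptotic BCL2 relative, rose by 0.97 against untreated on the log2 scale, and the proapoptotic genes Hrk and Bmf changed by -0.86 and -0.64, while Bid (0.94) and the caspase gene Casp6 (0.90) rose. Of 29 apoptosis genes and p53 targets 10 rose and 6 fell, or 10 and 7 adjusted over the list alone, and the list as a whole did not shift (camera adjusted p = 0.51). Against proNGF-WT at 4 h Mcl1 was at 1.06, Hrk at -0.93 and Bmf at -1.15.

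Odc1, which limits polyamine synthesis, rose by 1.96 at 4 h of NGF, and Gch1, an enzyme of the cofactor of tyrosine hydroxylase, by 1.17. Among transcription factors of the sympathoadrenal lineage Ascl1 rose (0.71) and Phox2a fell (-0.87). Of 18 catecholamine and chromaffin genes 3 rose and 3 fell. Chac1 (1.18) and Ppp1r15a (1.18), targets of the stress factor ATF4, rose at 1 h of NGF, and Atf4 itself (0.74). The stress and amino acid response list did not pass camera against untreated there, nor with slide as a block (camera adjusted p = 0.168). No set of ATF4 targets was tested. Furin, the convertase that cleaves proNGF, fell at 4 h with NGF (-0.50), proNGF-WT (-0.50) and proNGF-KR (-0.54) against the untreated array, the last 2 not without replicate 1 of their groups.

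Mature NGF raised 21 of 25 immediate early genes at 1 h, and at 4 h 19 of the 25, not all of them the same genes, were higher than in untreated cells, while 8 of 12 matrix protease genes had risen and 14 of 31 cell cycle genes had fallen. Neither precursor at its dose brought Egr1 and Fos at 1 h, or Mmp13 at 4 h, near the NGF level. The 2 precursors could not be separated from each other. What they share against untreated cells does not rest on the untreated array alone, but could come from the untreated RNA or its handling. The group medians of at least 0.5752 were taken over features chosen by their calls against that array. Arc, Srf and Btg2 rose from 1 h to 4 h with both precursors in a comparison free of the untreated sample. This may be a late precursor response, or may come from the slides, since time and slide coincide and no array crosses them. Time in culture after the medium change is also part of this comparison, as no untreated samples per time are labelled.

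Doses are labelled in ng/ml and differ between NGF and proNGF by mass. Whether they also differ in molar terms was not worked out, so the mass doses alone do not show unequal dosing. No series of doses was run, so a weaker response to proNGF cannot be split from a different one here. Untreated cells with fresh medium at 1 h and 4 h, with replicates and a dye swap, would settle which common changes are responses. A neutralizing antibody that binds mature NGF and spares proNGF, given with the precursors, would test whether Egr1, Klf4 and Klf6 respond to trace NGF.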
